A study of Mus musculus with 8 samples.

How the data were processed

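Liver RNA from 8 adult male mice was measured, 4 controls labelled wild type and 4 labelled as carrying a hepatic deletion of Rictor made with albumin-Cre and a floxed allele. Per the labels' protocols, the mice were fasted for 16 h and then given food for 3 h before the liver was taken. Per the labels' protocols, total RNA was isolated as Chirgwin and colleagues described, and 100 ng of total RNA was converted to biotinylated cDNA with the Ambion WT Expression Kit. Each sample was hybridised to its own Affymetrix Mouse Gene 1.0 ST array, a 1-colour array whose probes are spread along the whole transcript.

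The deposited table holds 1 value per probe set and array, 35556 probe sets in all. The submitters' processing notes name Affymetrix Expression Console, RMA and Partek, without versions, roles or order. RMA corrects the background, makes the distributions of the arrays equal by quantile normalisation and summarises the probes of a set on the log2 scale. The authors' deposited values were taken as log2 values; the base was read from their range and from the use of RMA, since the labels do not state it. The medians over all probe sets lay between 6.90 and 7.03, so the arrays were close to a common scale but not identical in distribution. Probe-level intensities were not used here, so background correction and summary could not be repeated. Because RMA equalises arrays, a change shared by most genes would not be seen in these values, and differences of dim probe sets are compressed.

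Probe sets were named through the platform annotation given with the series, with symbols brought up to date by Entrez identifier against a mouse RefSeq gene table (assembly GRCm38.p6). Of the probe sets, 21789 had exactly 1 gene symbol, 1621 had several and were not tested, and 12146 had no gene in that annotation. The identifiers of 21698 of the single-symbol probe sets matched the gene table. These probe sets represented 19938 genes, of which 999 had more than 1 probe set; such a gene was counted once, by the probe set with the highest mean over the 8 arrays. The genome build behind the probe sets is not given in the sources used here, so no coordinates are reported.

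The main comparison was a linear model per probe set with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), knockout-labelled minus control, two-sided, with equal array weights and no covariate. P-values were adjusted by the Benjamini-Hochberg method over the 21789 probe sets, with 0.05 as the threshold, and no filter on brightness. Errors of fold changes are moderated standard errors from this fit. Single values were also compared by an exact two-sided permutation test, for which 4 arrays against 4 give a smallest p of 0.0286. The number of arrays limits the precision of every value.

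A total of 31 gene lists was fixed before the data were examined: 4 primary lists, which cover fatty acid and triglyceride synthesis, glycolysis, gluconeogenesis and FoxO1 targets, 7 lists of markers of other cell types, and the remaining lists for other liver pathways. They were tested with camera in limma at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 31 lists. Beside it, camera with a correlation estimated for each list and fry were run. Of the 641 list members, 61 were not analysed here.

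Named genes followed a rule that was also fixed before the data were examined. It took 20 genes of insulin signalling and its liver targets, of which 19 were measured. It added the 12 genes with the largest rise and the 12 with the largest fall among the genes past the threshold, provided that all arrays of one group lay on one side of the other and leaving out predicted or unnamed gene models and genes of some large families. When no gene passes, as here, the rule takes the 12 genes with the smallest p in each direction, and these are given as values that did not pass; the conditions on separation and symbols were kept. From each list without a called member it took the pair with the smallest p. In all 99 different genes were taken by the rule.

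The replicate numbers in the labels were checked for pairing. The correlations between same-numbered arrays of their deviations from the group means were -0.0930, -0.125, -0.0400 and 0.0738, so the numbers were not treated as pairs. The correlation between any 2 arrays lay between 0.991 and 0.996, and no 2 arrays shared more than 14 identical values, so every array was counted as a separate sample.

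The procedure was tested on simulated data with known changes in 200 of 19938 genes, built for the comparison of 4 arrays with 4. It called 77.6% of genes changed 1.5-fold, 97.0% of genes changed 2-fold and 100% of genes changed 3-fold, with 9 of 19738 unchanged genes called. These rates describe the simulated arrays only. In the main comparison of the real arrays Rmrp differed 2.20-fold and Rps12 1.96-fold, and neither passed (limma adjusted p = 0.140 for both). The rates are therefore not the power of the real comparison, and a lack of calls there does not exclude changes of these sizes. Alternatives covered the variance model, array weights, normalisation, filters on brightness, all probe sets, the replicate number as a block, leaving out each array in turn, other thresholds, a plain two-sample test, and other forms of the list test. A fit without both arrays numbered 1 was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python.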

Results

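Gene expression was measured in the livers of 8 adult male mice that had been fasted for 16 h and refed for 3 h, a state in which insulin acts on the liver. Of these, 4 were controls and 4 were labelled as lacking Rictor in hepatocytes. Rictor is a defining subunit of mTOR complex 2 (mTORC2), a kinase complex that phosphorylates Akt downstream of the insulin receptor. The design has 1 comparison, knockout-labelled against control livers after refeeding, which asks how liver transcripts depend on hepatic mTORC2. The values are RMA expression values on the log2 scale, from 1 array per mouse, and the median over all probe sets ranged from 6.90 to 7.03 across the arrays. Differences below are log2 fold changes, knockout-labelled minus control, with n = 4 in each group.

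The Rictor probe set was not lower on the knockout-labelled arrays. Its mean was 9.40 ± 0.19 (SD, n = 4) in controls and 9.45 ± 0.22 (SD, n = 4) in the knockout-labelled group, a log2 fold change of 0.05 with a 95% interval from -0.23 to 0.32 (exact permutation p = 0.83). The lowest value, 9.15, belonged to knockout-labelled array 1, and the other 3 arrays of that group read 9.51, 9.68 and 9.47, against 9.47, 9.28, 9.23 and 9.64 in controls. A whole-transcript probe set can keep signal from exons outside the deleted part and from cells other than hepatocytes, and which exons it covers was not examined, so this probe set does not check the genotype labels. The groups are therefore named by their labels, and every direction below rests on those labels.

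On the knockout-labelled arrays the transcripts of 2 gluconeogenic enzymes had higher means than in controls, while Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a lower mean. Pck1 (phosphoenolpyruvate carboxykinase) differed by 0.55 (SE 0.14) and G6pc (glucose-6-phosphatase) by 0.56 (SE 0.17). Cyp7a1 differed by -0.46 (SE 0.12). All 4 knockout-labelled arrays lay below all 4 controls, but knockout-labelled array 1 (12.82) only just below control 1 (12.84). With all 8 arrays at equal weights none of these differences passed the correction over all probe sets (limma adjusted p = 0.204, 0.249 and 0.224), and 0 genes passed it in all. With array weights all 3 passed (0.67, 0.75 and -0.45; limma adjusted p = 0.0131, 0.0194 and 0.0388), as they did without knockout-labelled array 1 (0.71, 0.72 and -0.56; limma adjusted p = 0.00431, 0.0130 and 0.0153). The weights fall with an array's distance from the rest of its labelled group, so they favour the labels given. Under them 4 of 35 splits, the real one among them, called as many genes as the real split. Here and below, passing with array weights or without the arrays numbered 1 is not a separate test of a gene. The smallest adjusted p of any gene at equal weights was 0.140.

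Without adjustment, 2084 genes had a p under 0.05, 766 of them higher and 1318 lower on the knockout-labelled arrays, where chance alone would give 997. A plain two-sample test also called 0 genes. In 881 genes, or 4.42%, the 2 groups did not overlap, against 2.86% by chance. Both chance values are averages, genes vary together, and neither count was set against other splits of the arrays. The excess is therefore not a test. The count depended on the arrays numbered 1. With array weights estimated by limma, which gave knockout-labelled array 1 the lowest weight of 0.467, 707 genes passed, 262 higher and 445 lower. Without that array 877 genes passed, without control 1 59 passed, of which 46 were higher and 13 lower, and without both arrays numbered 1, a choice made after seeing the data, 1489 passed. Leaving out any other single array gave 0. Of the 99 named genes, 57 passed with array weights, 59 without knockout-labelled array 1, 16 without control 1, 69 without both arrays numbered 1, and 0 in the other 14 settings run for single genes.

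**Figure D1:**
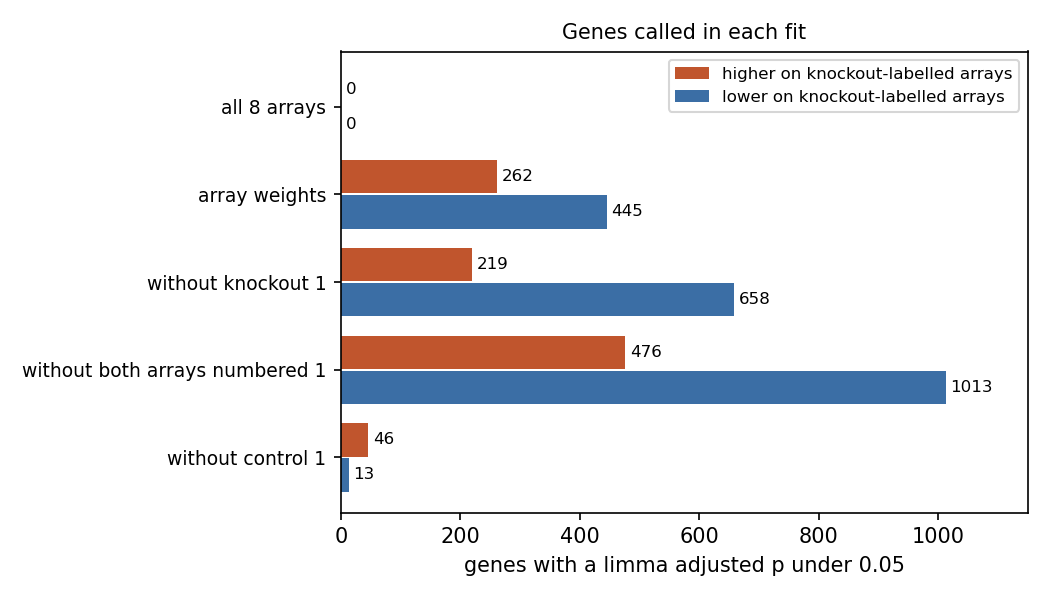
Number of genes with a limma adjusted p under 0.05 (horizontal axis) in the fit to all 8 arrays and in 4 other fits, as bars for genes higher and genes lower on the knockout-labelled arrays. The fit to all 8 arrays called 0 genes, and the fit without both arrays numbered 1 called 476 higher and 1013 lower.

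The arrays numbered 1 stood apart from the rest of their groups. On the first principal component, which held 35.8% of the variance, controls 2 to 4 lay between -0.344 and -0.298 and knockout-labelled arrays 2 to 4 between 0.410 and 0.458. Knockout-labelled array 1 lay at -0.310, and control 1 at -0.0293. The mean correlation of knockout-labelled array 1 with the other arrays of its own group was 0.992, and with the controls 0.995.

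Several insulin-responsive transcripts followed this pattern. Igfbp1, which insulin represses through FoxO1, had a mean of 8.01 ± 1.36 (SD, n = 4) in controls and 9.40 ± 1.11 (SD, n = 4) on the knockout-labelled arrays, a difference of 1.39 (SE 0.61; limma adjusted p = 0.436). Control 1 read 10.04 and knockout-labelled array 1 read 7.76, so that the spread within each group came mainly from these arrays. Irs2, the insulin receptor substrate that is also repressed after feeding, differed by 0.50 (SE 0.24; limma adjusted p = 0.473). Without both arrays numbered 1 the differences were 2.62 for Igfbp1 and 0.94 for Irs2 (limma adjusted p = 1.8e-07 and 8.7e-05). Both arrays were left out after seeing the data and lay toward the other group in these genes, so these p-values are not a test. With array weights the 2 genes did not pass (1.86 and 0.70; limma adjusted p = 0.0575 and 0.0553), and without knockout-labelled array 1 Irs2 passed and Igfbp1 did not (0.75 and 1.94; limma adjusted p = 0.0280 and 0.0633). Without both arrays Pck1 differed by 0.78, G6pc by 0.87 and Cyp7a1 by -0.60 (limma adjusted p = 0.00012, 6.7e-05 and 0.0043). The same limit holds for Pck1, G6pc and Cyp7a1. The adjusted p-values without both arrays were the lowest of these 5 genes among the 18 alternatives run for each, and the highest were 0.780, 0.804, 0.610, 0.653 and 0.623 in the order given.

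**Figure D2:**
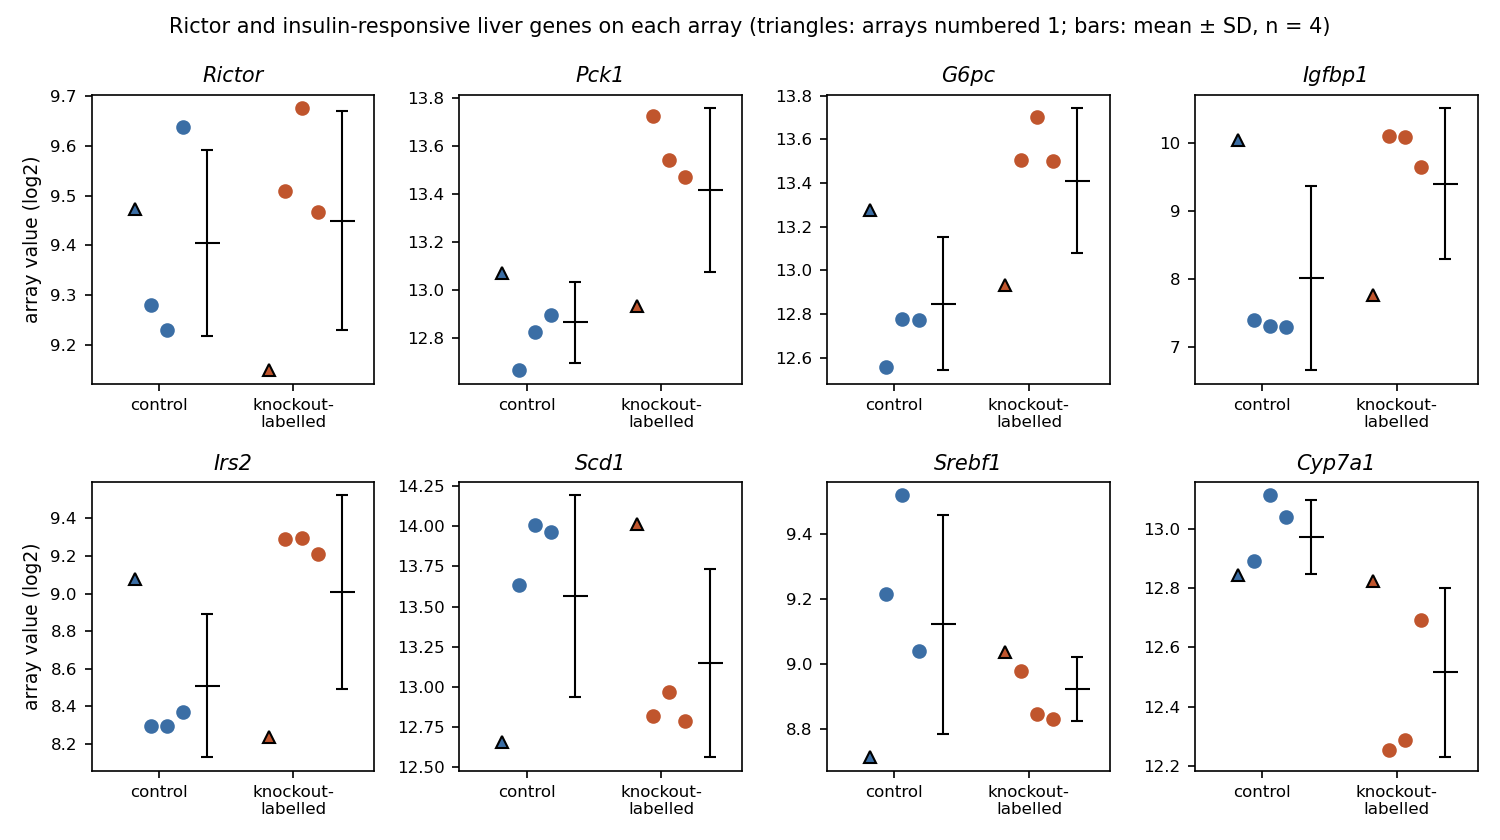
Array values on the log2 scale (vertical axis) of 8 genes in control and knockout-labelled livers, 1 point per array, with triangles for the arrays numbered 1 and bars for the mean ± SD (n = 4). Rictor overlaps between the groups, and Igfbp1 reads 10.04 on control 1 and 7.76 on knockout-labelled array 1.

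Of the 14 measured genes of the gluconeogenesis list, 11 had a higher mean on the knockout-labelled arrays, and the list mean was 0.14 above controls. The list was called by camera at the preset correlation (adjusted p = 0.00234), and not with an estimated correlation (adjusted p = 0.552) or by fry (adjusted p = 0.399). Over all genes 0 members passed, and adjusted over the list alone 4 did: Pck1, G6pc, Crtc2 and Cebpb. Crtc2, a coactivator of CREB on gluconeogenic genes, differed in the opposite direction, by -0.52 (SE 0.12; limma adjusted p = 0.157, and 0.0190 with array weights). Ppargc1a gave 0.10 by its brighter probe set and 0.60 by its other one, so no value of that gene is settled. The 20 FoxO1 targets had a mean of 0.19 above controls and a median of 0.09, with 15 higher and Igfbp1 at 1.39. They were called by camera (adjusted p = 0.00268) but not with an estimated correlation (adjusted p = 0.552) or by fry (adjusted p = 0.313). Adjusted over the FoxO1 list alone, 1 member, Pck1, passed. Pck1, G6pc, Ppargc1a and Tat belong to both lists, so the calls of the 2 lists are not independent. Without both arrays numbered 1 the list means were 0.21 for gluconeogenesis and 0.34 for the FoxO1 targets.

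The list of insulin-stimulated fatty acid and triglyceride synthesis was not called (camera adjusted p = 0.209). Its mean was 0.02 above controls, and from -0.0075 to 0.070 with single arrays left out. Of its members 14 of 23 measured were higher, and 0 passed over all genes or adjusted over the list alone. Members went both ways. Elovl5 differed by 0.29 (SE 0.09). It passed with array weights (limma adjusted p = 0.0458) but not without knockout-labelled array 1 (limma adjusted p = 0.105). Fasn (fatty acid synthase) differed by 0.35 (SE 0.14) and Acaca (acetyl-CoA carboxylase 1) by 0.24 (SE 0.13), whereas Scd1 (stearoyl-CoA desaturase 1) differed by -0.42 (SE 0.30), Scd2 by -0.44 (SE 0.12), Srebf1 by -0.20 (SE 0.15) and Mlxipl, which encodes the carbohydrate-responsive factor ChREBP, by -0.28 (SE 0.11). Scd1 read 12.66 on control 1 and 14.02 on knockout-labelled array 1, against group means of 13.57 and 13.15. Without both arrays numbered 1 Scd1 differed by -1.01, Scd2 by -0.57, Mlxipl by -0.37 and Fasn by 0.46 (limma adjusted p = 6.7e-05, 0.00724, 0.0134 and 0.0194). That fit was chosen after seeing the data, and in Scd1 and Scd2 both left-out arrays lay toward the other group. Its p-values are therefore not a test. Over the 18 alternatives run for each of these 4 genes, the values of that fit were the lowest adjusted p-values, and the highest were 0.890, 0.613, 0.764 and 0.776. Fasn and Scd2 also passed with array weights (0.50 and -0.50; limma adjusted p = 0.0397 and 0.0218) and without knockout-labelled array 1 (0.49 and -0.51; limma adjusted p = 0.0237 and 0.0243). Srebf1 and Acaca passed in none of their 18 alternatives, and single arrays moved their values, Srebf1 to -0.34 without control 1 and -0.066 without control 3, and Acaca to 0.13 without knockout-labelled array 3. Scd1 lay at -0.72 without control 1, -0.71 without knockout-labelled array 1 and -0.27 without control 3. The glycolysis list, of which 9 of 15 members were measured, had a mean of 0.11 and 7 members higher. It was called by camera (adjusted p = 0.0238) but not with an estimated correlation (adjusted p = 0.552), nor without control 2 (adjusted p = 0.0896) or knockout-labelled array 3 (mean 0.066, adjusted p = 0.182). Khk, the fructose-phosphorylating ketohexokinase, differed by 0.39 (SE 0.10) and was the 1 member that passed when adjusted over the list alone; with array weights it passed over all genes (limma adjusted p = 0.0262). Pklr, liver pyruvate kinase, differed by 0.02 (SE 0.16).

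Lists of mitochondrial and lipid-oxidising genes had the smallest camera p-values. The fatty acid oxidation and PPARalpha list had a mean of 0.24, with 20 of 25 measured members higher (camera adjusted p = 3.95e-08). Acadvl, the very long chain acyl-CoA dehydrogenase, differed by 0.56 (SE 0.13) with all knockout-labelled arrays above all controls. Its margin was small, with control 1 at 10.93 and knockout-labelled array 1 at 10.95. The peroxisomal thiolase gene Acaa1b differed by 0.61 (SE 0.15). Adjusted over the list alone 7 members passed, all of them higher, and over all genes 0. The list of respiratory complex I and oxidative phosphorylation had a mean of 0.16, with 20 of 26 members higher (camera adjusted p = 7.78e-06), and 9 members passed when adjusted over the list alone. Its subunit genes Ndufa4 and Cox4i1 differed by 0.45 (SE 0.12) and 0.57 (SE 0.16). With array weights Acadvl, Acaa1b, Ndufa4 and Cox4i1 passed over all genes (limma adjusted p = 0.0115, 0.0194, 0.0240 and 0.0309). Not every member of the oxidative phosphorylation list was higher. With array weights 4 of its members passed as higher and 1 as lower. At equal weights 11 higher and 1 lower member had an unadjusted limma p under 0.05. Neither list was called with an estimated correlation (adjusted p = 0.552 for both) or by fry (adjusted p = 0.313 for both). Control 1 lay at 0.21 above the control mean in the first list and at 0.15 in the second.

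The list of cholesterol synthesis and uptake had a mean of 0.14, with 17 of 20 measured members higher (camera adjusted p = 0.000903, and adjusted p = 0.552 with an estimated correlation). The mean was 0.091 without control 4 and 0.088 without knockout-labelled array 4, and camera still called the list in both cases. Hmgcs1, a cytosolic enzyme of the mevalonate pathway, differed by 0.59 (SE 0.17), and 0 members passed when adjusted over the list alone. The circadian clock list had a mean of -0.24, with 14 of 18 measured members lower (camera adjusted p = 0.00234, and adjusted p = 0.552 with an estimated correlation). Fry, tested for change in either direction, called this list alone (adjusted p = 0.0283). Adjusted over the list alone 6 members passed: Per2, Per3, Nr1d2, Dbp, Ciart and Usp2. Ciart differed by -1.14 (SE 0.27) and Usp2 by -0.66 (SE 0.15). With array weights Hmgcs1, Ciart and Usp2 passed over all genes (limma adjusted p = 0.0197, 0.0150 and 0.0150).

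**Figure D3:**
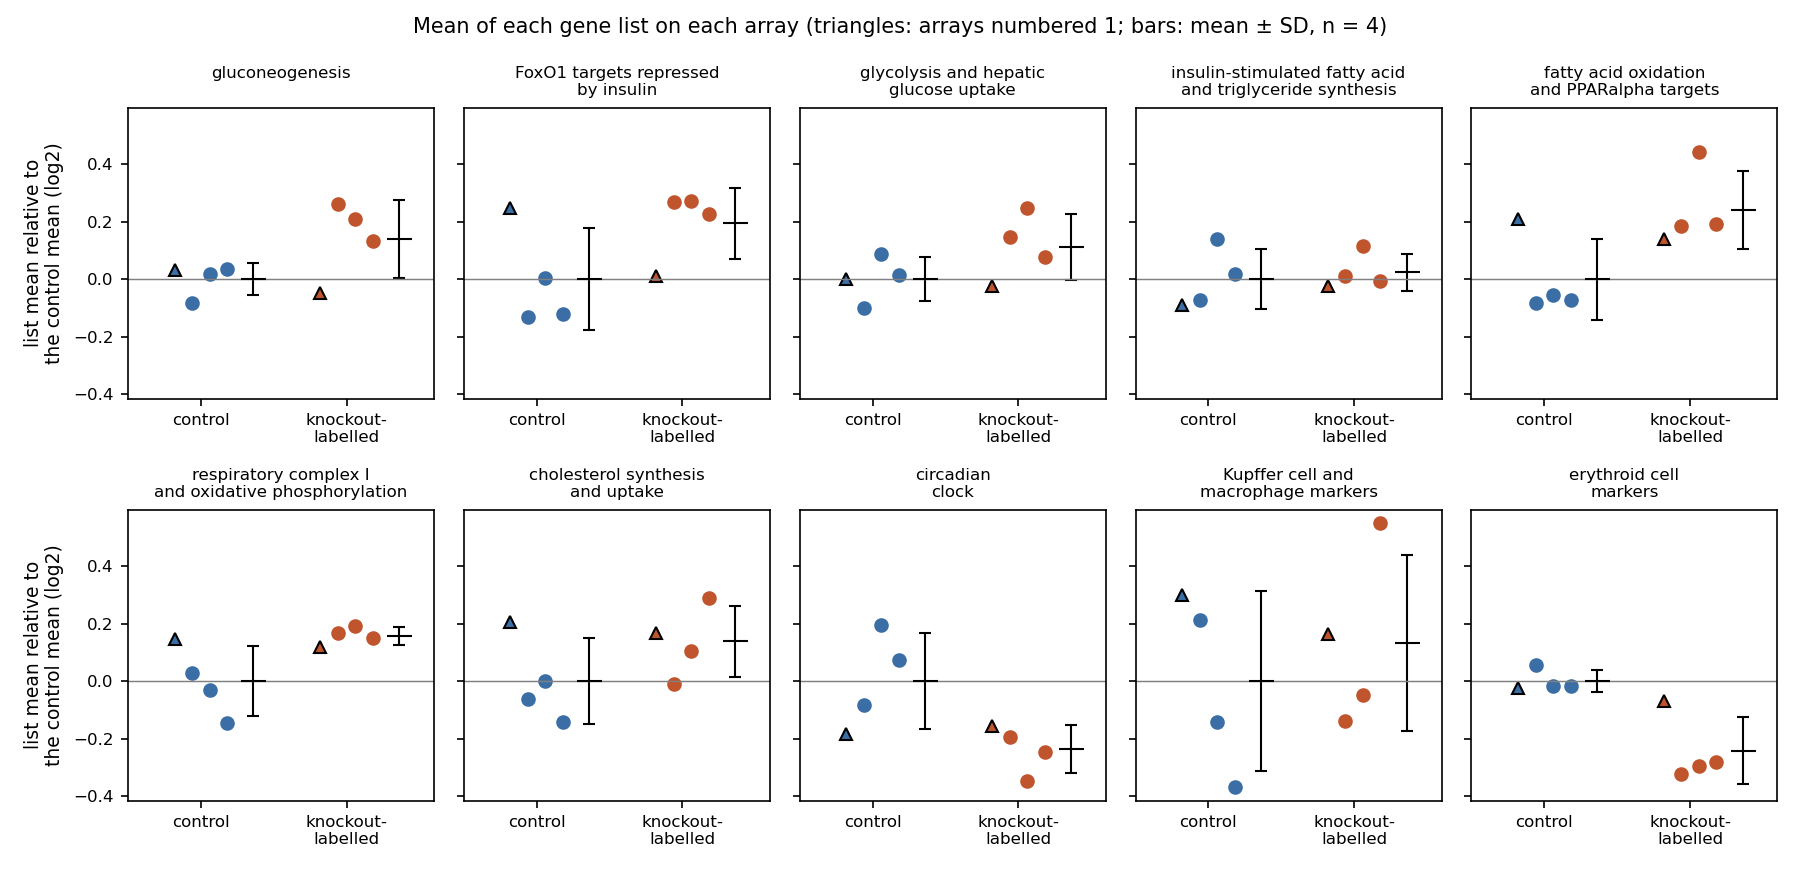
Mean of each of 10 gene lists on each array relative to the control mean, in log2 units (vertical axis), with triangles for the arrays numbered 1 and bars for the mean ± SD over arrays (n = 4). In the FoxO1 target list control 1 lies at 0.25, beside knockout-labelled arrays 2 to 4 at 0.27, 0.27 and 0.23, and knockout-labelled array 1 lies at 0.01.

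Of the genes of the mTOR complexes and the PI3K-Akt pathway, Rictor left out, 31 of 33 were measured, with a list mean of -0.02 (camera adjusted p = 0.824). Mtor differed by 0.15 (SE 0.11), Rptor by 0.03 (SE 0.10), Mapkap1, which encodes the mTORC2 subunit Sin1, by -0.05 (SE 0.09), Akt2 by -0.22 (SE 0.10) and Foxo1 by -0.11 (SE 0.10). With single arrays left out Mtor lay from 0.089 to 0.23, Mapkap1 from -0.094 to -0.031 and Foxo1 from -0.16 to -0.060. The other probe set of Akt2 gave -0.13. Rheb, the small GTPase that activates mTOR complex 1, differed by 0.54 (SE 0.13). Prr5l differed by -0.27 (SE 0.08) and passed in none of its 17 alternatives. At equal weights with all 8 arrays none of these passed (the lowest limma adjusted p was 0.188, for Rheb). Rheb passed with array weights (0.64; limma adjusted p = 0.0150), without knockout-labelled array 1 (0.62; limma adjusted p = 0.0193) and without both arrays numbered 1 (0.71; limma adjusted p = 0.00224), and the highest of its 18 alternatives was 0.600. The list mean lay from -0.039 to -0.0021 with single arrays left out.

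The genes with the smallest p among those that separated the groups are given as values, since none passed (limma adjusted p from 0.140 to 0.143). Higher on the knockout-labelled arrays were Rmrp, the RNA of RNase MRP (1.14, SE 0.20), Rps12 (0.97, SE 0.17), Calm2 (0.89, SE 0.18), Sptssa, a subunit of serine palmitoyltransferase (0.68, SE 0.11), Rrs1 (0.67, SE 0.12), Srp14, Rpl23, Uqcrh, Atox1, Ndufaf2, Tomm7 and Txndc17. Rps12 and Rpl23 encode ribosomal proteins, and Uqcrh, Ndufaf2 and Tomm7 encode mitochondrial proteins. The 14 probe sets of Rps12 gave from 0.75 to 0.97, several of them with identical values. Lower were Ndufaf1, an assembly factor of respiratory complex I (-0.95, SE 0.18), Hdac4 (-0.76, SE 0.16), Phf5a (-0.73, SE 0.15), Rab22a (-0.70, SE 0.14), Narf (-0.64, SE 0.13), Snx32, Macroh2a1, Pabpn1, Gar1, Tlcd3a, Tmem14a and Alyref. The second probe sets of Hdac4 and Tlcd3a gave -0.05 and -0.01, so these 2 genes rest on 1 probe set each. The second probe set of Calm2 gave 0.29 (SE 0.11; limma adjusted p = 0.350), well below the 0.89 of its brighter one, so the size of its difference is not settled. All of these 24 genes passed in the same direction with array weights, without knockout-labelled array 1 and without both arrays numbered 1, and 13 of them without control 1. They were picked from these same arrays for a small p and full separation, so passing in these fits is not a separate test. The separation of Snx32 was very narrow, with knockout-labelled array 1 at 8.439 and control 1 at 8.440.

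Among other hepatocyte pathways camera called no list. List means, with camera adjusted p, were -0.05 for bile acid synthesis and transport (0.736), -0.07 for glycogen metabolism (0.672), 0.02 for lipoprotein assembly (0.209), -0.10 for the unfolded protein and integrated stress response (0.256), 0.01 for amino acid catabolism (0.209), -0.12 for xenobiotic metabolism (0.151) and 0.04 for NRF2 targets, whose median was -0.02 (0.553). They were -0.15 for growth hormone signalling and male-biased genes (0.123), -0.08 for female-biased genes (0.792), 0.05 for the acute phase response (0.209), -0.06 for the interferon response (0.946), -0.05 for the cell cycle (0.453), 0.005 for ribosome biogenesis, with a median of -0.003 (0.558), -0.12 for pericentral markers (0.149) and 0.001 for periportal markers (0.260). Among members, Fgf21 differed by 0.39 (SE 0.16), Fabp2 by 0.70 (SE 0.21), Aldh1a1 by -0.34 (SE 0.11), Saa4 by -0.58 (SE 0.19) and the periportal Hsd17b13 by 0.47 (SE 0.10), none of which passed at equal weights with all 8 arrays. The last 4 passed with array weights (limma adjusted p = 0.0208, 0.0275, 0.0259 and 0.0117) and without knockout-labelled array 1 (limma adjusted p = 0.0171, 0.0111, 0.00873 and 0.00614), while Fgf21 passed in none of its 17 alternatives. Fgf21 read 7.50 on knockout-labelled array 3, and without that array its difference was 0.20. Saa1, an acute phase protein, differed by 1.35 (SE 0.44) with 8.78 on knockout-labelled array 1, and by 0.83 without that array. Single arrays moved several list means. The male-biased list lay at -0.25 without knockout-labelled array 1 and -0.23 without control 1, against -0.071, -0.089 and -0.095 without knockout-labelled array 2, control 2 and knockout-labelled array 3. The stress response list lay at -0.048 without knockout-labelled array 2 and -0.051 without control 3, bile acid synthesis at -0.027 without knockout-labelled array 3 and glycogen metabolism at -0.043 without knockout-labelled array 2. With single arrays left out the cell cycle list lay from -0.077 to -0.013 and lipoprotein assembly from 0.0071 to 0.032. The means of the amino acid, NRF2, female-biased, acute phase, interferon, ribosome biogenesis and periportal lists changed sign with the array left out. With array weights camera also called the xenobiotic (adjusted p = 0.0361), male-biased (adjusted p = 0.0158) and pericentral (adjusted p = 0.0439) lists, all lower. With an estimated correlation and equal weights they were not called (adjusted p = 0.625, 0.798 and 0.625). They were also called after quantile normalisation again (adjusted p = 0.0301, 0.0301 and 0.0399), and without both arrays numbered 1 the xenobiotic (adjusted p = 0.0490), male-biased (adjusted p = 0.000154) and stress response (adjusted p = 0.0154) lists were. Single arrays decided further calls: without knockout-labelled array 1 the stress response (adjusted p = 0.0367), interferon (adjusted p = 0.0299) and male-biased (adjusted p = 0.00998) lists were called as lower, the last also without control 1 or knockout-labelled array 4 (adjusted p = 0.0129 and 0.0344). Without control 3 the pericentral list was called as lower (adjusted p = 0.0205), and without knockout-labelled array 3 the acute phase list was called as higher (adjusted p = 0.0177). With an estimated correlation over all 8 arrays the stress response, interferon and acute phase lists were not called (adjusted p = 0.821, 0.981 and 0.751).

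Markers of other cell types were compared in the same way. The 17 Kupffer cell and macrophage markers had a mean of 0.13, with 14 higher (camera adjusted p = 0.0101, and adjusted p = 0.751 with an estimated correlation). The list mean fell close to 0 without knockout-labelled array 4, which lay 0.55 above the control mean (-0.0078, adjusted p = 0.396), and equally without control 4, which lay at -0.37 (0.0085, adjusted p = 0.313). Camera's call also ended without control 3 (adjusted p = 0.142) or knockout-labelled array 1 (adjusted p = 0.0505), and among the brighter genes, where the mean was 0.072 (adjusted p = 0.275). Fry did not call the list (adjusted p = 0.697). The mean was higher without control 1 (0.23), control 2 (0.20) or knockout-labelled array 2 (0.22), where the call was kept. Over its 21 alternatives the adjusted p ranged from 0.000153 to 0.751, and 14 kept the call. The spread of this list over the controls was 0.31 (SD, n = 4), larger than the difference. The erythroid list, with 8 of 12 markers measured, had a mean of -0.24 and a median of -0.06, with 7 lower. Fry called it (adjusted p = 0.0447), camera did not (adjusted p = 0.119), and its exact permutation p of 0.0286 was the smallest that 4 arrays against 4 allow (adjusted p = 0.443 over the 31 lists). Its member Car1 lay furthest from 0, at -1.18 (SE 0.26; limma adjusted p = 0.143, and 0.0115 with array weights). The remaining lists were not called: endothelial markers at -0.03 (adjusted p = 0.946), where camera's direction was up, stellate cell and fibroblast markers at -0.02 with a median of 0.03 (adjusted p = 0.736), cholangiocyte markers at -0.09 (adjusted p = 0.453), lymphocyte and neutrophil markers at -0.11 (adjusted p = 0.123) and adipose and pancreas markers at -0.04 (adjusted p = 0.631). The cholangiocyte mean lay at -0.16 without knockout-labelled array 1, -0.044 without control 3 and -0.040 without knockout-labelled array 4, and the lymphocyte mean at -0.17 without knockout-labelled array 1, -0.059 without control 2 and -0.068 without knockout-labelled array 3. With single arrays left out the adipose and pancreas list lay from -0.075 to -0.0083, and the endothelial and stellate means changed sign. With array weights the lymphocyte list was called as lower (mean -0.19, adjusted p = 0.00862), whereas with an estimated correlation and equal weights it was not (adjusted p = 0.751). It was also called without control 3 (adjusted p = 0.0157), control 4 (adjusted p = 0.0139) or knockout-labelled array 1 (adjusted p = 0.0367).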

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

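The test of exchanged labels, the test of knockout-labelled array 4 and the reading of the splits with equal weights were set after their results were seen, and the fit without both arrays numbered 1 was chosen after seeing the data; the other tests in this part were set before their results. The values of named genes and list means were screened in each group of 4 for an array that lay far from the other 3, by Dixon's critical value. Of 260 groups, 26 held such an array, where chance gives about 13, and the groups are not independent of each other. Knockout-labelled array 1 was the array in 10 of the 26 and control 1 in 5.

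On control 1, relative to the mean of the other 3 controls, Igfbp1 lay 2.71 and Irs2 0.76 higher on the log2 scale, while Mlxipl (-0.49) and Snx32 (-0.36) lay lower, and the fatty acid oxidation and PPARalpha list lay 0.28 higher. On knockout-labelled array 1, relative to the other 3 of its group, Scd1 lay 1.16, Ndufaf1 0.81, Hdac4 0.67, Bckdhb 0.61, Phkg2 0.40 and Lum 0.29 higher, and Irs2 (-1.03), Bckdha (-0.32) and Tomm7 (-0.28) lay lower. The erythroid marker list lay 0.23 higher on that array.

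The other arrays gave 11 such values. On knockout-labelled array 3, Fgf21 lay 0.79, Ehd3 0.20, Gsr 0.17 and the list of mTOR complexes and the PI3K-Akt pathway 0.080 higher than the rest of the group. On control 4 Hdac4 lay 0.46 higher and Xbp1 lay lower (-0.13). On control 3 Alyref (-0.12) and Klf1 (-0.093) lay lower. On control 2 Prr5l (-0.17) and the gluconeogenesis list (-0.11) lay lower and the erythroid marker list lay 0.076 higher.

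The arrays numbered 1 of both groups stood apart, and 3 technical explanations were tested. For brightness and gene length, the rank correlations across genes of the deviation of knockout-labelled array 1 were 0.218 and 0.0556. Both lay within those of the other arrays, which reached -0.381 for brightness on knockout-labelled array 2 and 0.184 for gene length on control 4. For gene length this argues against a trend particular to knockout-labelled array 1. A trend with brightness stays open. Its 0.218 was the largest positive value, and the reference means of knockout-labelled arrays 2 to 4 include array 1. An exchange of the labels of the 2 arrays stays open: on an axis from controls 2 to 4 to knockout-labelled arrays 2 to 4 with the midpoint at 0, knockout-labelled array 1 lay at -0.322, among the left-out controls (-0.336 to -0.275), but control 1 lay at -0.0283, between them and the left-out knockout-labelled arrays (0.235 to 0.343). A wrong label of knockout-labelled array 1 alone, or incomplete deletion in that mouse, may account for that array but not for control 1, which lay above all 3 left-out controls, so neither gives the whole pattern. A difference between mice in how much they ate in 3 h was not tested, and it and the exchange cannot be told apart with these arrays, because Rictor's probe set did not separate the groups.

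The number of called genes was set against other splits of the same arrays. With equal weights the real split called 0 genes, a count that all 35 of 35 splits must reach, so this comparison cannot decide about chance. The highest other split called 470. That split exchanges the arrays numbered 1 and restates their place on the first principal component. With array weights the real split called 707 genes, 4 of 35 splits gave as many and the highest other gave 1177, again the exchange of both arrays numbered 1. The next, with 1028 and 812 genes, exchanged knockout-labelled array 1 with control 4 and with control 3. Each of these splits moves knockout-labelled array 1 to the controls. The comparison therefore does not separate chance from the place of that array, and chance cannot be excluded. Without knockout-labelled array 1 the real split called 877 genes, 1 of 35 splits gave as many and the highest other gave 460; this is the smallest share that 35 splits can give, and since the array was singled out from 8 left out in turn, chance cannot be excluded for that count. Without both arrays numbered 1 the real split called 1489 and the highest other 1, and 10 splits are too few to give a share under 0.05 (1 of 10 gave as many).

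The gene list calls by camera at the preset correlation are no more frequent than in other groupings: the real split called 8 lists, 17 of 35 splits called as many, and the highest other called 14, so chance cannot be excluded for this count. For the Kupffer cell and macrophage list, a high macrophage content of knockout-labelled array 4 alone stays open: the mean log2 fold change of the list was -0.00776 without that array, but 0.00852 without control 4, so a low value of that control accounts for it as well. For the lists of fatty acid oxidation and of oxidative phosphorylation, a trend of all genes with brightness and gene length is argued against: both means (0.24 and 0.16) lay at percentile 100 of 10000 random lists matched on both properties, which averaged -0.03 in each case. That percentile describes these arrays and does not replace a test over mice. The length used was that of the gene, with a median of 17.7 kb over all genes, so a trend with transcript length was not tested. A difference by genotype stays open for both lists as a hypothesis that these arrays do not settle.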

How the results depend on the processing

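The fit without both arrays numbered 1 was chosen after seeing the data; all other settings were fixed before. The count of 0 genes held without the trend, with robust variances, with quantile normalisation again, with centring, with both filters on brightness, with all probe sets, with an adjusted p under 0.1, with 1.5-fold as a minimum and in the plain two-sample test. It did not hold with array weights (707 genes, 262 higher and 445 lower), without both arrays numbered 1 (1489, 476 higher and 1013 lower), or when single arrays were left out (0 to 877, with 0 to 219 higher and 0 to 658 lower; 877 without knockout-labelled array 1 and 59 without control 1). Of these calls, 570 genes were shared by the fits with array weights, without knockout-labelled array 1 and without both arrays numbered 1, all in the same direction. These fits share most of their arrays, so the shared calls and directions do not test the genes again. With the replicate number as a block the count was 0 and no list changed its side of the threshold; the numbers did not pair the arrays. The cause of the other changes was not tested. The scaling moved the median of all genes little (-0.02 as deposited, -0.002 after quantile normalisation, -0.003 after centring). Signal over background was not analysed here, so what it limits is unknown.

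The glycolysis list lost its call with quantile normalisation again (0.12), in the brighter genes (0.11) and on ranks (0.11). With single arrays left out its mean lay from 0.066 to 0.16. The call was then lost only without control 2 (0.078) or knockout-labelled array 3 (0.066). Of its 21 alternatives, 14 kept the call. With an estimated correlation and with fry, the glycolysis (0.11), gluconeogenesis (0.14) and FoxO1 target (0.19) lists kept their means and lost their calls. Camera's adjusted p ranged up to 0.552 over the 21 alternatives, from lows of 0.00862, 0.000109 and 1.07e-05; for cholesterol synthesis, fatty acid oxidation, oxidative phosphorylation and the clock, 19 of 21 alternatives kept the call, which was lost with an estimated correlation and with fry. Of the 99 named genes, 57 passed with array weights and 69 without both arrays numbered 1. The fatty acid synthesis list ranged from -0.0075 to 0.070 and Rictor from -0.030 to 0.15 with single arrays left out.

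Values close to 0 changed sign in some settings. With array weights this held for the mTOR and PI3K-Akt list (0.0038), acute phase (-0.018), ribosome biogenesis (-0.00032) and periportal markers (-0.023). It held with quantile normalisation again for periportal markers (-0.0051), in the brighter genes for acute phase (-0.015) and the cell cycle (0.033), and with the mean of all probe sets for ribosome biogenesis (-0.0014). Without both arrays numbered 1 it held for Rptor (-0.024), acute phase (-0.090), ribosome biogenesis (-0.090), periportal (-0.013), endothelial (0.027) and stellate markers (0.0021). With single arrays left out the ranges were -0.036 to 0.084 for Rptor, -0.12 to 0.12 for Pklr, -0.097 to 0.23 for Ppargc1a, -0.010 to 0.027 for amino acid catabolism, -0.13 to 0.012 for female-biased genes, -0.19 to 0.032 for interferon response, -0.053 to 0.052 for ribosome biogenesis, -0.017 to 0.032 for periportal, -0.069 to 0.022 for stellate and -0.071 to 0.0075 for endothelial markers, -0.061 to 0.12 for acute phase, -0.0015 to 0.076 for NRF2 targets and -0.0078 to 0.23 for Kupffer markers.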

Other observations

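The groups of clock genes below and their test were chosen after the clock list had been seen. The set of ribosomal protein genes was also formed after seeing the data; its test against matched lists was fixed before that result. Ribosomal protein genes had higher means on the knockout-labelled arrays: 47 of 59 measured genes were higher, with a mean log2 fold change of 0.28 and a median of 0.25. Without adjustment 31 of them had a p under 0.05, all higher, and 21 passed with array weights, all higher. Control 1 lay at 0.24 above the control mean, and the knockout-labelled arrays at 0.18, 0.28, 0.34 and 0.31, so the groups overlapped (exact permutation p = 0.0571). Camera gave p = 3.6e-23 at the preset correlation and p = 0.0649 with an estimated one. Of the 59 genes, 37 have more than 1 probe set, and signal from their many processed copies was not separated. Random lists matched on brightness and gene length averaged 0.001, against 0.28 for the set. That argues against a trend of all genes with these properties as the source. The set's mean lay at percentile 100 of the 10000 matched lists. Because the set was formed after seeing the data, neither that rank nor the camera p-values are a test of it. The length used was that of the gene, with a median of 3.3 kb in this set and 17.7 kb over all genes. Transcript length was not matched, so a trend with it was not tested. The percentile does not replace a test over mice.

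The clock genes that peak in antiphase to Arntl were lower on the knockout-labelled arrays in 11 of 11 cases, with a mean log2 fold change of -0.41 (exact permutation p = 0.0286, unadjusted and the smallest possible). The 4 measured genes that peak with Arntl had a mean of 0.08 (SE over members 0.05; exact permutation p = 0.371), and 3 of them were higher. Means of opposite sign are what a shift of the clock's phase, or of the time of sampling or feeding, would give, so this stays a candidate explanation; the positive mean of 0.0837 is within the spread between arrays and does not separate it from lower output of the clock. The hour at which each liver was taken is not given in the sources used here.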
